A study of Arabidopsis thaliana with 33 samples.

How the data were processed

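The series holds 33 arrays of Arabidopsis thaliana root, 8 from sorted cell populations and 25 from sections of 2 roots. Per the labels, RNA was extracted with a micro-scale column kit and amplified in 2 cycles by the Affymetrix protocol before hybridisation as biotin-labelled cRNA. The deposited values are a linear expression intensity per probe set, all above 0 and with array medians near 1, which the authors had scaled in a way they did not state. Background correction, summarisation and normalization are not given in the sources used here. The design text names 2 to 3 replicates per reporter line, and 1 array per line was analysed here; whether its values are from a single array or a mean of those replicates is not stated. Values were taken as deposited and converted to log2 with no offset and no filter.

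Probe sets were paired with genes through the deposited platform annotation: 13513 of 22746 probe sets listed 1 gene, 503 listed several and 8730 were not listed. By gene ID 13436 of the single-gene probe sets matched the TAIR10.1 annotation, which was used for names and no coordinates. A named gene was a gene with a symbol other than a locus code (1579 probe sets), a definition settled after the annotation was read. Genes with several probe sets are named by the one with the highest mean level.

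Zone comparisons used the 24 section arrays of the 12 positions shared by both roots. The log2 values of the sections of a zone in a root were averaged, which gave 6 values, and limma (version 3.58.1 in R 4.3.3) fitted zone and root, with root as a block and a moderated two-sided test per probe set. P values were adjusted by Benjamini and Hochberg over all probe sets of each comparison at a threshold of 0.05, and the fit had 2 residual and 3.06 prior degrees of freedom. The block was checked first: the difference between the roots correlated between positions, with a median of 0.477 over 66 pairs of positions (range -0.233 to 0.834), so the arrays of a root share a signature. The array titles of the 2 roots follow different naming series, so a batch difference cannot be told apart from a difference between the roots. Variation over the 12 positions was tested with limma's moderated F test on all 24 arrays, with position and root as terms, and the 11 steps between neighbours are contrasts of that fit. With a position left at 1 array, that array is assumed to vary like the others.

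Before the data were examined 25 gene lists of root cell types, tissues and processes were fixed (292 genes, 3 left out because the reference gives their symbol to another locus), together with the comparisons, the rule for named genes and most of the other settings tried. Single-gene probe sets measured 37 of these genes, and 9 lists had at least 2 members. A further 22 lists (645 genes, 473 measured) were chosen after the annotation was read and before any gene's values were seen. Lists were tested with limma camera, which compares a list with all other probe sets, at an inter-gene correlation of 0.01 and also with the correlation estimated, and with fry. The estimate rests on 2 residual degrees of freedom, and camera then refers its statistic to a t distribution on those 2. Hardly any list can pass that test after adjustment. A call lost with an estimated correlation therefore does not show that correlation between genes made the call. Adjustment ran within each family of lists over the 3 comparisons, 27 and 66 tests. The least number of 2 members and the split into families were settled after a first run, with a minimum of 3 members, had been seen.

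The genes named in the zone comparisons are, first, the 6 largest rises and the 6 largest falls among named genes past the threshold with the same sign in both roots. Second, for each list described, they are up to 4 passing members in the direction of the list median and the largest passing one in the other direction, or the 2 largest values where none passed. Per population they are the 5 largest differences among genes highest in that population, and for the columella the 8 largest in each direction. Values given beyond that rule, for single-member lists, were chosen after they were seen.

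Sorted populations and the columella have 1 array each and were described without a test, by log2 differences, by counts at 4-fold (and 2-fold above the highest other population) and by the percentile of each list median among 10000 random lists matched on mean level in 50 bins. For each population the 100 probe sets with the largest difference were also tested by camera in the zone comparisons, over 24 tests. These sets come from sorted arrays that share no array with the sections.

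The steps were tested on simulated data built on the design: of 100 probe sets changed by log2 2, 65 were recovered between zones and 97 along the positions, and of 100 changed by log2 1 the numbers were 18 and 61. Alternatives tried were no replicate block, the fit to all 24 arrays, quantile normalization, offsets of 50 and 1 before log2, leaving out the dimmest 30% of probe sets, a trended prior variance, leaving out each section array, each root alone, other set sizes and other references. The number of arrays limits the precision, since each zone value rests on 2 roots. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.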

Results

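The series profiled gene expression in the root of Arabidopsis thaliana on 33 Affymetrix arrays of 22746 probe sets. Of root cells, 8 kinds, each marked by a fluorescent reporter line, had been freed as protoplasts from seedlings of 5 to 6 days and sorted by fluorescence, with 1 array per population here. The populations were phloem pole pericycle (S17), protophloem and metaphloem (S32), hair cells (COBL9), xylem pole pericycle (JO121), meristematic xylem (S4), phloem companion cells (SUC2), a mixed pericycle, xylem and phloem line (J2501) and lateral root primordia (RM1000). The other 25 arrays came from 2 single roots of 7 days that had been cut across their length, 13 sections from root 1 and 12 from root 2. Each root gave 6 meristematic sections, 2 elongation sections and 4 maturation sections of about 500 micrometres, counted from the tip, and root 1 gave a columella section as well. Sections of 1 root are not independent, so the root was the replicate (n = 2 roots), and the number of arrays limits the precision.

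Array medians lay between 0.79 and 1.04 in the deposited intensity. The spread of the log2 values differed between arrays: the SD was 0.137 for the columella section, 0.426 for elongation section 2 of root 1 and 0.634 to 1.53 for the other 31 arrays. Spearman correlations between the roots, taken across probe sets, were 0.591 at elongation section 2 and up to 0.946 at the other positions; probe sets are not independent replicates. Between the sorted populations they were 0.738 to 0.936. The description of elongation section 2 of root 1 names root 2, while its title and the number of sections per root place it in root 1, where it was counted. Counts that changed without it are given with each comparison.

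The first comparison asked which transcripts differ between the elongation zone, where cells lengthen, and the meristematic zone, where they divide. GH9C1 (AT1G48930), an endoglucanase of the cell wall, was 8.28-fold higher in the elongation zone (log2 3.05 ± 0.166 SE, n = 2 roots, limma adjusted p = 0.0094). XTH18 (AT4G30280), a xyloglucan endotransglucosylase, rose 5.81-fold (log2 2.54 ± 0.186, adjusted p = 0.0123), and EXPA18 (AT1G62980), an expansin of root hairs, rose 5.80-fold (2.54 ± 0.216, adjusted p = 0.0136). The defensin gene PDF2.5 (AT5G63660) fell by 3.03 on the log2 scale (SE 0.117, adjusted p = 0.0094) and the drought-induced gene DI21 (AT4G15910) fell by 2.55 (SE 0.119, adjusted p = 0.0094). Also among the largest rises were TBL38 at log2 2.81 ± 0.188, the dehydrin COR47 at 2.77 ± 0.371 and the beta-glucosidase BGLU46 (AT1G61820) at 2.76 ± 0.222. COR47 also changed within the meristematic zone, by log2 -4.435 from section 1 to 2 (limma adjusted p = 0.0328). Among the largest falls were DRT100 at -2.68 ± 0.500, TBL39 (AT2G42570) at -1.85 ± 0.165, the signalling peptide gene RALFL34 at -1.83 ± 0.123 and ULT1, a regulator of meristem size, at -1.79 ± 0.184. In all, 543 probe sets were higher and 1167 lower in the elongation zone at an adjusted p under 0.05, and 391 and 613 of them changed at least 2-fold.

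Of 114 measured cytosolic ribosomal protein genes, 50 fell, 0 rose and 64 did not pass (median log2 change -1.36; limma camera adjusted p = 1.32e-30); AT1G27400 fell by 2.01 ± 0.344 and AT1G07070 by 2.01 ± 0.200. Of 7 core histone genes 5 fell (median -1.28, adjusted p = 1.17e-06), among them AT2G37470 at -2.01 ± 0.118 and HTB2 at -1.77 ± 0.144. Of 27 kinesin and mitotic apparatus genes 6 fell and 21 did not pass (median -0.38, adjusted p = 1.03e-07), with 3xHMG-box2 at -1.69 ± 0.133 and the spindle checkpoint gene BUB3.1 at -1.05 ± 0.151. In the RNA polymerase core group 1 of 10 genes fell, NRPA2 at -0.86 ± 0.146 (list median -0.48, adjusted p = 0.000236). Each of these 4 list calls was lost with an adjusted p = 0.53 with an estimated correlation. That run of camera has 2 degrees of freedom, here and below, so the loss can reflect its low power alone. Adjusted over each list alone, 102 ribosomal protein, 7 core histone, 11 kinesin and 5 RNA polymerase genes fell.

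All 3 measured members of the root hair list rose in the elongation zone: EXPA18, EXPA7 at log2 2.33 ± 0.192 and SCN1 at 0.62 ± 0.121 (median 2.33, adjusted p = 0.00176; adjusted p = 0.932 with an estimated correlation). Adjusted over the list alone, 3 rose as well. In the xyloglucan endotransglucosylase family 4 of 10 genes rose, XTH18, XTH21 (AT2G18800) at 1.73 ± 0.159, EXGT-A3 at 1.16 ± 0.213 and XTH33 at 0.96 ± 0.171 (median 0.78, adjusted p = 6.77e-05). Of 10 extensin genes, which encode wall glycoproteins, 3 rose (median 0.66, adjusted p = 0.000445), with HRGP1 at 2.17 ± 0.307 and AT1G23720 at 1.72 ± 0.243. Of 55 class III peroxidase genes 9 rose and 46 did not pass (median 0.22, adjusted p = 7.52e-06), with AT1G30870 at 3.91 ± 0.204 and AT3G21770 at 3.21 ± 0.559. In the expansin family 3 of 18 rose, EXLA1 at 2.03 ± 0.282 among them, and EXPA9 fell by 0.77 ± 0.146 (median 0.17, adjusted p = 0.0117). In the UGT glycosyltransferase family 2 of 47 rose, UGT74B1 at 1.68 ± 0.232 and UGT72E3 at 0.84 ± 0.145, while UGT85A2 fell by 1.12 ± 0.169 (median 0.16, adjusted p = 0.00171). For these 5 families the calls were lost with an adjusted p = 0.53 with an estimated correlation. Adjusted over each list alone, 5 xyloglucan endotransglucosylase, 6 extensin, 13 peroxidase, 4 expansin and 2 UGT genes rose, and 2 peroxidase, 1 expansin and 1 UGT gene fell. Without elongation section 2 of root 1 the median was 0.03 for the expansin family, 0.06 for the UGT family and -0.90 for the ribosomal protein genes, and after quantile normalization it was 0.26 for the expansin family.

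The count of 1710 probe sets fell to 193 with no replicate block, which leaves out the root block (81 higher and 112 lower), to 1018 after quantile normalization (459 and 559) and to 206 with an offset of 50 (13 higher and 193 lower). It was 564 without elongation section 1 of root 1 (63 higher and 501 lower), 995 without elongation section 2 of root 1 (501 higher and 494 lower), 1096 without maturation section 3 of root 1 (371 and 725) and 730 without elongation section 1 of root 2 (193 and 537). The share of higher probe sets was 31.8% in the fit above, 45.1% after quantile normalization and 6.31% with the offset of 50. Of the 12 genes with the largest changes 8 passed with every single section array left out. COR47 (adjusted p = 0.115) and XTH18 (adjusted p = 0.0766) did not pass without elongation section 1 of root 1, and DRT100 (adjusted p = 0.333) and TBL39 (adjusted p = 0.165) did not pass without elongation section 2 of root 1. DRT100 also missed the threshold without meristematic section 3, 5 or 6 or maturation section 3 of root 1 (adjusted p = 0.0514, 0.0586, 0.0566 and 0.0508), and without meristematic section 6 or elongation section 1 of root 2 (0.0567 and 0.0732). Of the 33 list members called, 7 passed with every single array left out, 22 after quantile normalization and 8 with no replicate block.

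**Figure D1:**
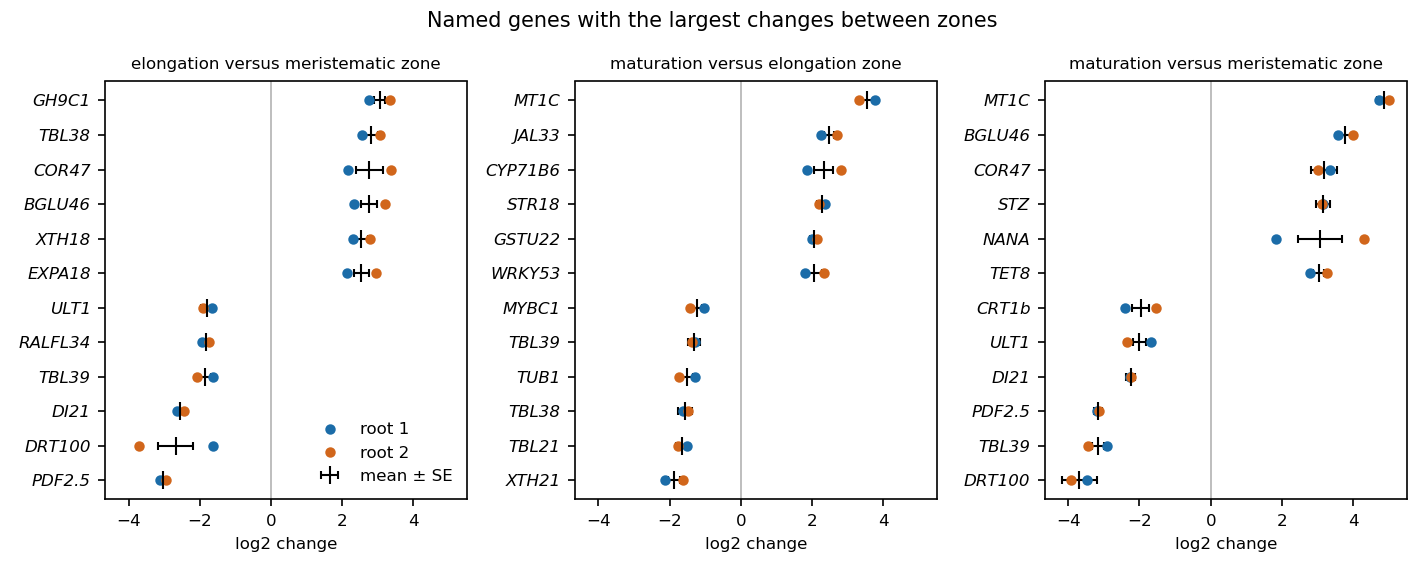
Log2 change between zones for the named genes with the largest rises and falls in each of the 3 comparisons. Dots show root 1 and root 2, and bars show the mean ± SE of limma (n = 2 roots). The rule of choice put both dots of each gene on the same side of 0, and the means ran from MT1C at 4.86 to DRT100 at -3.69 in the comparison of maturation with the meristematic zone.

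The second comparison set the maturation zone, where cells differentiate, against the elongation zone. The metallothionein gene MT1C (AT1G07610) rose 11.6-fold (log2 3.54 ± 0.196 SE, n = 2 roots, limma adjusted p = 0.0166), the jacalin lectin gene JAL33 (AT3G16450) rose 5.57-fold (2.48 ± 0.153, adjusted p = 0.0166) and the sulfurtransferase gene STR18 (AT5G66170) rose 4.84-fold (2.28 ± 0.144, adjusted p = 0.0166). XTH21 fell by 1.88 (SE 0.159, adjusted p = 0.0231) and the beta-tubulin gene TUB1 (AT1G75780) fell by 1.51 (SE 0.164, adjusted p = 0.0358). The other large rises were the cytochrome P450 gene CYP71B6 at 2.33 ± 0.266, the glutathione transferase gene GSTU22 at 2.07 ± 0.114 and the transcription factor gene WRKY53 at 2.06 ± 0.219. The other large falls were TBL21 at -1.64 ± 0.187, TBL38 at -1.57 ± 0.188, TBL39 at -1.32 ± 0.165 and MYBC1 at -1.24 ± 0.150. In all 188 probe sets were higher and 48 lower, and 179 and 46 of them changed at least 2-fold.

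Of 4 genes of the extended suberin list, for the lipid polymer of mature root cell walls, 2 rose (median 1.28, camera adjusted p = 4.74e-07): AT1G74460 at 2.31 ± 0.125 and AT2G23540 at 1.56 ± 0.144. Of 7 ER body genes, for defence compartments of the endoplasmic reticulum, 2 rose, JAL33 and NAI2 at 1.46 ± 0.182 (median 0.88, adjusted p = 1.17e-06). In the TBL family, whose members acetylate wall polysaccharides, 3 of 22 fell, TBL21, TBL38 and TBL39 (median -0.11, adjusted p = 0.0264), and in the xyloglucan endotransglucosylase family 1 of 10 fell, XTH21 (median -0.29, adjusted p = 0.014). These 4 calls were lost with an adjusted p = 0.53 with an estimated correlation. Adjusted over each list alone, 4 suberin and 6 ER body genes rose, and 5 TBL and 4 xyloglucan endotransglucosylase genes fell. The TBL call was also lost after quantile normalization (adjusted p = 0.0518) and with an offset of 50 (adjusted p = 0.0554), and the xyloglucan endotransglucosylase call was lost with that offset (adjusted p = 0.066) and without the 4 root 1 arrays of the lowest spread (adjusted p = 0.0604). Without elongation section 2 of root 1 the xyloglucan endotransglucosylase median was -0.83 and the TBL median -0.05, and after quantile normalization they were -0.60 and -0.06.

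Of the 3 measured wound and stress genes 2 rose, WRKY53 and the zinc finger gene STZ (AT1G27730) at 1.79 ± 0.192 (median 1.79, adjusted p = 0.000697; adjusted p = 0.932 with an estimated correlation). Adjusted over the list alone, 3 rose. Of 55 class III peroxidase genes 7 rose and 48 did not pass, with AT5G64120 at 3.68 ± 0.327, AT4G36430 at 3.17 ± 0.400, AT1G14550 at 2.28 ± 0.203 and AT2G37130 at 2.18 ± 0.156 (adjusted p = 0.00234; adjusted p = 0.574 with an estimated correlation), and 12 rose and 1 fell adjusted over the list alone. The median of that list was 0.04, and -0.11 in root 1 alone, 0.08 without elongation section 2 of root 1 and 0.01 after quantile normalization. In the kinesin list 1 of 27 genes rose, 3xHMG-box2 at 1.28 ± 0.133 (median 0.16, adjusted p = 0.00125; adjusted p = 0.616 with an estimated correlation), and the median was 0.27 without elongation section 2 of root 1. Among 43 plastid-encoded photosystem and electron transport genes 0 passed by limma (1 at an unadjusted p under 0.05), against a list median of -0.26 (adjusted p = 0.0126; adjusted p = 0.745 with an estimated correlation), and the median was 0.07 in root 1 alone. Of its members psbM stood at 0.89 ± 0.558 and rbcL at -0.60 ± 0.260, neither past the threshold.

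The 236 probe sets became 79 with no replicate block, the fit without the root block (69 higher and 10 lower), 69 after quantile normalization (65 and 4), 5 with an offset of 50 (5 and 0) and 654 with a trended prior variance (476 and 178). The count was 99 without elongation section 1, 137 without elongation section 2, 472 without maturation section 1, 120 without maturation section 2, 67 without maturation section 3 and 407 without maturation section 4 of root 1; it was 119 without meristematic section 6 and 46 without elongation section 1 of root 2. MT1C and STR18 passed with every single section array left out, and STR18 did not pass after quantile normalization. JAL33 missed the threshold without maturation section 3 of root 1 (adjusted p = 0.071) and GSTU22 without elongation section 2 of root 1 (adjusted p = 0.19). XTH21 missed it without any of 3 arrays, CYP71B6 and WRKY53 without any of 6, TBL21 without any of 9, MYBC1 and TUB1 without any of 10, TBL39 without any of 11 and TBL38 without any of 12. The highest adjusted p was 0.127 for XTH21, 0.111 for WRKY53 and 0.358 for TBL21, each without elongation section 1 of root 2. It was 0.138 for CYP71B6 without maturation section 3 of root 1. Without elongation section 1 of root 1 it was 0.135 for MYBC1, 0.445 for TUB1, 0.463 for TBL39 and 0.296 for TBL38. The log2 changes in that run were -1.136, -0.94, -0.71 and -1.138, in the same order. Of the 15 list members called, 0 kept a limma call with every single array left out, 3 kept it after quantile normalization and 4 with no replicate block.

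The third comparison set the maturation zone against the meristematic zone. MT1C rose 29.0-fold (log2 4.86 ± 0.196 SE, n = 2 roots, limma adjusted p = 0.00347) and BGLU46, which acts on glucosides of lignin precursors, rose 13.7-fold (3.78 ± 0.222, adjusted p = 0.00395). STZ rose 8.88-fold (3.15 ± 0.192, adjusted p = 0.00405) and the tetraspanin gene TET8 (AT2G23810) rose 8.17-fold (3.03 ± 0.149, adjusted p = 0.00395). TBL39 fell by 3.17 (SE 0.165, adjusted p = 0.00395) and PDF2.5 fell by 3.16 (SE 0.117, adjusted p = 0.00347). COR47 at 3.18 ± 0.371 and the aspartic protease gene NANA at 3.07 ± 0.624 were the other large rises. MT1C and COR47 were not even over the meristematic zone. From its section 1 to 2 they changed by log2 -4.078 and -4.435 (limma adjusted p = 8.32e-06 and 0.0328), a drop that the zone mean hides. The other large falls were DRT100 at -3.69 ± 0.500, DI21 at -2.25 ± 0.119, ULT1 at -2.01 ± 0.184 and the calreticulin gene CRT1b at -1.97 ± 0.234. In all 1514 probe sets were higher and 1608 lower, and 1079 and 818 of them changed at least 2-fold.

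Of 114 cytosolic ribosomal protein genes 83 fell and 31 did not pass (median -1.57, camera adjusted p = 6.53e-28), with AT5G22440 at -2.24 ± 0.212 and AT3G16780 at -2.21 ± 0.318. Of 7 core histone genes 5 fell (median -1.38, adjusted p = 1.66e-05), with AT2G37470 at -2.07 ± 0.118, HTB2 at -1.90 ± 0.144 and HTB1 at -1.85 ± 0.199. Of 7 tubulin genes 3 fell, TUB5 at -1.71 ± 0.181, TUB1 at -1.66 ± 0.164 and TUB7 at -0.72 ± 0.123 (median -0.60, adjusted p = 0.0207). In the RNA polymerase core list NRPB6B fell by 0.84 ± 0.139 and 9 of 10 did not pass (median -0.41, adjusted p = 0.0031). These 4 calls were lost with an adjusted p = 0.53 with an estimated correlation. Adjusted over each list alone, 102 ribosomal protein, 7 core histone, 3 tubulin and 1 RNA polymerase gene fell. In the kinesin list 2 of 27 fell, AT3G45850 at -0.80 ± 0.115 and BUB3.1 at -0.80 ± 0.151 (median -0.25, adjusted p = 0.00133; adjusted p = 0.616 with an estimated correlation). Among 7 DNA replication enzymes 1 fell, the histone chaperone gene ASF1B at -0.89 ± 0.184 (median -0.30, adjusted p = 0.0385; adjusted p = 0.574 with an estimated correlation), and 2 fell adjusted over the list alone. The tubulin call was lost without elongation section 2 of root 1 (adjusted p = 0.0589), in the fit to all 24 arrays (adjusted p = 0.0911), with an offset of 50 (adjusted p = 0.0624) and without the 4 root 1 arrays of the lowest spread (adjusted p = 0.115). Its median in these runs was -0.60, -0.60, -0.024 and -0.54, in the same order. The DNA replication call was lost with an offset of 50 (adjusted p = 0.0795) or of 1 (adjusted p = 0.0535).

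Of 55 class III peroxidase genes 26 rose from meristematic to maturation zone, 2 fell and 27 did not pass (median 0.69, adjusted p = 4.24e-08), with AT5G64120 at 4.62 ± 0.327, AT5G66390 at 4.50 ± 0.610, AT5G64100 at 4.21 ± 0.197 and, in the other direction, AT2G43480 at -0.71 ± 0.134. All 4 measured genes of the extended suberin list rose (median 1.47, adjusted p = 3.55e-05), among them AT1G74460 at 2.31 ± 0.125 and FACT, a caffeoyltransferase gene, at 0.86 ± 0.162. Of 10 extensin genes 4 rose, with HRGP1 at 3.00 ± 0.307 and AT5G06630 at 2.52 ± 0.485 (median 0.67, adjusted p = 6.52e-05). Of 7 ER body genes 3 rose: JAL33 at 1.93 ± 0.153, the beta-glucosidase gene PYK10 at 1.55 ± 0.247 and NAI1 at 0.74 ± 0.131 (median 0.52, adjusted p = 0.00239). In the UGT family 7 of 47 rose, with UGT87A2 at 2.22 ± 0.313 and UGT74B1 at 1.52 ± 0.232 (median 0.10, adjusted p = 0.00155), and in the tau glutathione transferase family 3 of 11 rose, with GSTU25 at 1.28 ± 0.152 and GSTU22 at 1.01 ± 0.114 (median 0.24, adjusted p = 0.0126). These 6 calls were lost with an adjusted p = 0.53 with an estimated correlation. Adjusted over each list alone, 29 peroxidase, 4 suberin, 4 extensin, 5 ER body, 11 UGT and 3 tau glutathione transferase genes rose, and 3 peroxidase genes fell. The tau glutathione transferase call was also lost in the fit to all 24 arrays (adjusted p = 0.058), and the UGT median was 0.05 after quantile normalization. The expansin, xyloglucan endotransglucosylase, GH9, TBL and pectin methylesterase lists had no call in this comparison (camera adjusted p = 0.132, 0.0619, 0.981, 0.977 and 0.0841).

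Of the 3 root hair genes 2 rose, EXPA18 at 2.30 ± 0.216 and EXPA7 at 2.14 ± 0.192 (median 2.14, adjusted p = 0.00812; adjusted p = 0.932 with an estimated correlation), and 2 rose adjusted over the list alone. The root hair call was lost with an offset of 50 (adjusted p = 0.0699). Of the 3 wound and stress genes 2 rose, STZ and WRKY53 at 2.59 ± 0.219 (median 2.59, adjusted p = 0.00512; adjusted p = 0.932 with an estimated correlation), and 2 rose adjusted over the list alone. In the SWEET sugar exporter family 2 of 16 rose, SWEET17 at 0.91 ± 0.167 and SWEET16 at 0.91 ± 0.137, both transporters of the vacuole (median 0.09, adjusted p = 0.0267; adjusted p = 0.574 with an estimated correlation), a call lost after quantile normalization (adjusted p = 0.0646). Of the 43 plastid-encoded genes 0 passed by limma (9 at an unadjusted p under 0.05), with psaI at -0.98 ± 0.406 and psbT at -0.82 ± 0.275 (median -0.38, adjusted p = 0.00122; adjusted p = 0.698 with an estimated correlation).

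The 3122 probe sets became 730 with no replicate block, the fit without the root block (441 higher and 289 lower), 2535 after quantile normalization (1318 and 1217), 451 with an offset of 50 (109 and 342) and 7218 in the fit to all 24 arrays (3394 and 3824). The count was 1609 without elongation section 1 of root 1 (886 and 723), 2000 without elongation section 2 of root 1 (1078 and 922) and 1982 without elongation section 1 of root 2 (1024 and 958). The balance of higher and lower probe sets thus depended on the scaling. Of the 12 genes with the largest changes 10 passed with every single array left out. NANA did not pass without maturation section 2 of root 1 (adjusted p = 0.0975) or elongation section 1 of root 2 (adjusted p = 0.0725), nor after quantile normalization. DRT100 did not pass limma without elongation section 2 of root 1 (adjusted p = 0.0729), where its log2 change was still -3.69. Of the 48 list members called, 19 passed with every single array left out, 38 after quantile normalization and 21 with no replicate block.

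The other lists fixed in advance had no camera call in the 3 comparisons. In the expansin and xyloglucan wall loosening list 2 of 8 genes rose between the meristematic and elongation zones, XTH18 and XTH21 (median 0.24, adjusted p = 0.0955; 2 rose adjusted over the list alone), and 1 fell from elongation to maturation (2 fell adjusted over the list alone). From meristematic to maturation zone 2 of the 8 rose, XTH20 at 2.55 ± 0.550 and XTH18 at 2.28 ± 0.186, and XTH19 fell by 1.41 ± 0.253; adjusted over the list alone 3 rose and 2 fell. In the pericycle and lateral root initiation list 1 of 3 genes rose in that comparison, PUCHI at 0.88 ± 0.191 (adjusted p = 0.0446; list median 0.59, adjusted p = 0.0647), and 2 rose adjusted over the list alone; LBD16 stood at 0.43 ± 0.138 between the first zones. In the wound and stress list STZ rose by 1.36 ± 0.192 between the meristematic and elongation zones (list median 0.53, adjusted p = 0.357; 1 rose adjusted over the list alone).

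Of the mitotic kinase genes measured for the mitotic cell cycle, AUR1 stood at -0.87 ± 0.181 (adjusted p = 0.0558) and AUR2 at -0.13 ± 0.155 between the meristematic and elongation zones; 0 of 2 passed by limma over all probe sets (1 at an unadjusted p under 0.05), and 1 fell adjusted over the list alone. In the later step 1 of the 2 rose adjusted over the list alone, AUR1 standing at 0.67 ± 0.181. The stem cell niche (3 genes), starch synthesis (2 genes), auxin response (3 genes) and type-A response regulator (2 genes) lists had 0 members past the threshold in any of the 3 comparisons by limma, over all probe sets or adjusted over the list alone. At an unadjusted p under 0.05 limma gave 1 gene of the stem cell niche list (from meristematic to maturation zone) and 1 of the auxin response list (in each comparison with the maturation zone), and 0 elsewhere in these lists. Their values between the first zones were -0.23 ± 0.111 for BBM, -0.09 ± 0.154 for JKD, -0.07 ± 0.134 for SBE2.2, -0.03 ± 0.134 for APL3, 0.16 ± 0.671 for GH3.3, -0.03 ± 0.118 for IAA30, 0.05 ± 0.160 for RR16 and -0.03 ± 0.122 for ARR15. From elongation to maturation zone GH3.3, which conjugates auxin, stood at 1.75 ± 0.671 (adjusted p = 0.395). Lists with 1 measured gene were not tested as lists. Among these genes HCT, of monolignol synthesis, rose by 2.11 ± 0.284 between the first zones (adjusted p = 0.0259), and LHW, an early xylem regulator, fell by 0.90 ± 0.131 (adjusted p = 0.029). PRL stood at -0.95 ± 0.194 (adjusted p = 0.0538) for DNA replication. GUT2 stood at 0.21 ± 0.149 for the xylem secondary wall, OPS at 0.33 ± 0.118 for protophloem, SWEET11 at 0.05 ± 0.118 for companion cells, COB at -0.02 ± 0.185 for primary wall cellulose and DFR at -0.02 ± 0.122 for flavonoids.

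Of the lists added after the annotation was read, 5 had no camera call in any of the 3 comparisons: the GH9 endoglucanase family (15 genes), iron deficiency regulators (7), pectin methylesterases and cell separation (5), auxin conjugation and IAA repressors (11) and the beta-glucosidase family (20). Their camera adjusted p values between the first zones were 0.851, 0.851, 0.0619, 0.708 and 0.213. Single members did pass limma. From meristematic to maturation zone 4 beta-glucosidase, 2 pectin methylesterase, 1 GH9 and 1 auxin conjugation gene rose, and 1 beta-glucosidase and 2 GH9 genes fell. Median, mean and test did not share a sign from elongation to maturation zone for the core histone, auxin response, UGT, tau glutathione transferase, pectin methylesterase, auxin conjugation and beta-glucosidase lists, nor from meristematic to maturation zone for the auxin response, type-A response regulator and auxin conjugation lists. Across both families camera called 4 of 27 tests of the lists fixed in advance and 30 of 66 tests of the added lists. When the correlation was estimated 0 of either kept the call, with 0 and 5 tests at an unadjusted p under 0.05. With 2 degrees of freedom that run could hardly pass any list after adjustment, so it does not decide whether the calls rest on correlated genes. With fry, which tests whether the genes of a set move on balance in one direction and compares them with no other genes, 3 and 5 tests passed. The 3 were the wound and stress list in each comparison, and the 5 were core histones and extended suberin (2 comparisons each) and the TBL family (1 comparison).

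**Figure D2:**
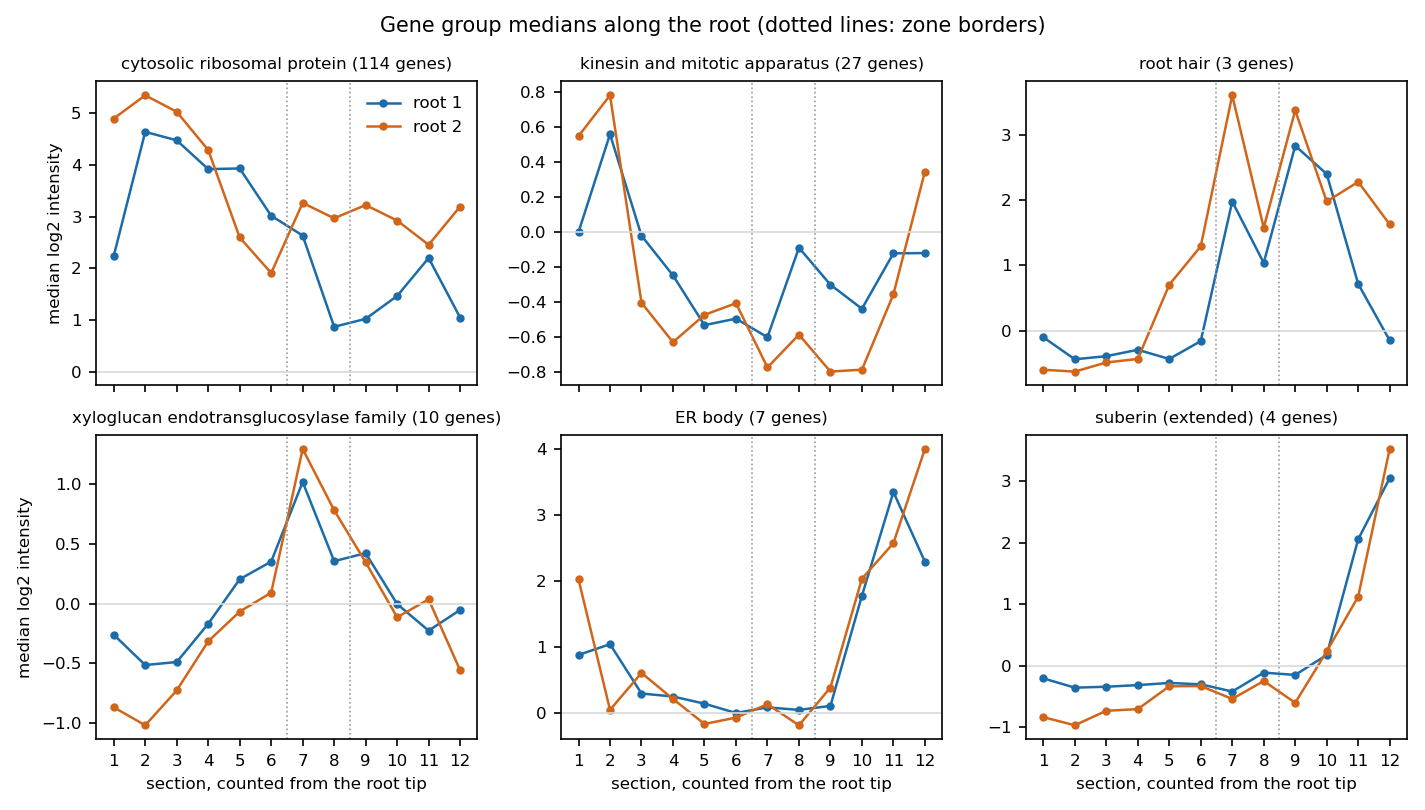
Median log2 intensity of 6 gene lists at each of the 12 section positions, counted from the root tip, in root 1 and root 2; dotted lines mark the zone borders. The extended suberin median reached 3.05 in root 1 and 3.52 in root 2 at the last section, and the xyloglucan endotransglucosylase median was highest at elongation section 1, at 1.02 and 1.29.

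A further question was where along the root expression varied at all. By limma's F test over the 12 positions 4378 probe sets varied (19.3% of all; 7129 at an unadjusted p under 0.05). Meristematic section 2 held the highest mean for 1532 of them, maturation section 2 for 595, maturation section 3 for 549 and elongation section 1 for 495. The log2 SD at meristematic section 2 was 1.038 in root 1 and 1.452 in root 2, the latter the largest of the section arrays. Wide spread may add to its count, and peaks were not counted after quantile normalization. Over all probe sets, called or not, the order differed: elongation section 2 held the highest mean for 6006, meristematic section 2 for 4618 and meristematic section 6 for 1851. Of the varying probe sets 32 had their highest mean at elongation section 2, whose root 1 array has a log2 SD of 0.426 and the highest median of all arrays (1.04). Without that array the numbers over all probe sets were 4566, 4711 and 2758, and of 3914 that varied 159 had their highest mean at elongation section 2 and 1330 at meristematic section 2. The ribosomal protein list had its highest median at meristematic section 2, 4.64 in root 1 and 5.35 in root 2, and core histone medians there were 2.80 and 3.45. The count was 2442 with no replicate block, the fit without the root block, 2114 with an offset of 50 and 2570 without meristematic section 2 of root 2.

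Between neighbouring sections 148 changes passed over the 11 steps. From meristematic section 1 to 2, 11 probe sets rose and 58 fell, and from elongation section 1 to 2, 0 rose and 31 fell. Elongation section 2 includes the root 1 array of narrow spread (log2 SD 0.426, against 0.992 at elongation section 1 of that root). Part of these falls, and of the rises in the step out of that section, may reflect that spread, which was not tested. From meristematic section 6 to elongation section 1, 6 rose. From elongation section 2 to maturation section 1 and from there to maturation section 2, 9 rose at each step; at the last 2 steps 8 and 7 rose and 2 and 3 fell. From meristematic section 2 to 3, 4 changed. Over the 3 steps from meristematic section 3 to 6, 0 passed by limma, with 602, 328 and 348 at an unadjusted p under 0.05. The total was 67 with no replicate block, the fit without the root block, 439 after quantile normalization, 529 with an offset of 50 and 286 with a trended prior variance. It was 93, 97, 94 and 242 without elongation section 1, elongation section 2, maturation section 2 and maturation section 4 of root 1. It was 824, 71, 516 and 253 without meristematic section 1, meristematic section 2, elongation section 2 and maturation section 4 of root 2.

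The sorted populations were compared by the log2 difference of each array to the mean of the other 7; with 1 deposited column per population, which may be 1 array or a mean of several, there are no replicates and no test. The hair cell array held the most probe sets at least 4-fold above that mean and 2-fold above the highest other array, 568, with the wall genes GH9C1 at 17.6 intensity units against 0.706 in the others (a log2 difference of 4.64) and EXPA7 at 16.9 against 0.823 (20.5-fold). TBL21 was 34.6-fold, NAI2 19.1-fold and the glycosyltransferase gene UGT71C1 14.7-fold higher there. The protophloem and metaphloem array held 404, with NTL 52.2-fold, GSTF4 48.2-fold, the calmodulin-like gene CML30 34.9-fold, TBL45 26.4-fold and GSTU18 24.4-fold higher. The meristematic xylem array held 216, with the protease genes SBTI1.1 11.3-fold, SCPL45 9.32-fold and scpl35 6.79-fold and EXPA15 9.36-fold higher; SAH7, 10.4-fold above the mean, was 1.13-fold above the highest other array and is not among them. The companion cell array held 84, with ATC 21.9-fold, GSTU23 11.6-fold, the ubiquitin-conjugating enzyme gene UBC29 at a log2 difference of 3.46 and ROXY2 6.22-fold higher. The glucosinolate transporter gene GTR2, 6.79-fold above the mean, was 1.07-fold above the highest other array and is not counted there. The phloem pole pericycle array held 79, with the sugar exporters SWEET11 17.2-fold and SWEET3 6.72-fold, MGL 6.52-fold and FDH 6.03-fold higher, but not ATSBT5.2, 6.25-fold above the mean and 1.48-fold above the highest other array. The lateral root primordia array held 51, with EXLA3 9.57-fold and EXO 6.76-fold higher. Not among these 51 were CCR2, an enzyme of lignin synthesis, JAL33 and EXLB1, which were 7.86-fold, 6.72-fold and 6.39-fold above the mean and 1.66-fold, 1.73-fold and 1.68-fold above the highest other array. The xylem pole pericycle and mixed J2501 arrays held 5 each, and they had the smallest log2 spread of the 8 (SD 0.997 and 0.879). Their largest differences were XTH21 at 9.10-fold, PDF2.5 at 4.84-fold, SQN at 3.26-fold, the mitochondrial gene nad2 at 2.00-fold and TRM28 at 1.92-fold for the first. For J2501 they were OSM34 at 2.49-fold, IAA20 at 2.22-fold, RSU1 at 2.17-fold, APK1A at 2.13-fold and OLEO3 at 1.96-fold. These counts depend on which populations are compared. All arrays but that of hair cells are of pericycle, xylem, phloem or primordia by their labels, and J2501 spans tissues of other lines. A gene shared equally by several lines cannot be counted for any of them. After quantile normalization 4 of the 8 counts moved by over 1.5 times. The reporter genes SUC2 and COBL9 themselves had 0 single-gene probe sets in the annotation. For 15 of the 40 genes named, NTL, GSTF4 and TBL21 among them, the mean of the other arrays (0.435 to 0.796) lay below the median of every sorted array (0.822 to 0.914). Their folds rest on dim values whose background is not known, so the folds are uncertain and their order is not read. The total of 1412 was 631 with an offset of 1. With an offset of 50 it was 0, which was fixed in advance: the highest value of any sorted array, 78.9, is too low for 4-fold at that offset.

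List medians in each population were placed among 10000 random lists of the same mean level. The random lists draw genes independently, while genes of a list can move together, so an extreme percentile is a description and no test. The root hair list stood highest in hair cells (median log2 difference 3.28, percentile 100, 3 genes), as did extensins (1.52, percentile 100, 10 genes). In meristematic xylem the ribosomal protein list (1.14, percentile 100), the kinesin list (1.15, percentile 100), core histones (1.32, percentile 99.7) and tubulins (1.39, percentile 99.4) were high. The pericycle and lateral root initiation list was high in lateral root primordia (2.00, percentile 99.99), with PUCHI at 2.51 and LBD16 at 2.00. Plastid-encoded genes were high in the protophloem and metaphloem array (2.57, percentile 100, 43 genes). The ribosomal protein list was lowest in phloem pole pericycle (-1.41, percentile 0).

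To relate cell types to the axis, the 100 probe sets with the largest difference for each population were tested in the zone comparisons. Camera called 17 of 24 tests. With an estimated correlation 0 passed, and the 17 had a camera adjusted p between 0.294 and 0.513. With fry 0 passed as well. Over all 24 tests, 2 had an unadjusted p under 0.05 with an estimated correlation and 7 with fry. Of the hair cell set 43 probe sets rose and 6 fell between the meristematic and elongation zones (median 0.83, adjusted p = 4.98e-13; adjusted p = 0.294 with an estimated correlation). Of the xylem pole pericycle set 26 rose and 2 fell in the same comparison (median 0.49, adjusted p = 7.9e-10; adjusted p = 0.294 with an estimated correlation). From meristematic to maturation zone 37 of the lateral root primordia set rose and 3 fell (median 0.52, adjusted p = 1.22e-13; adjusted p = 0.294 with an estimated correlation), and 33 of the phloem pole pericycle set rose and 0 fell (median 0.67, adjusted p = 3.87e-14; adjusted p = 0.294 with an estimated correlation). Of the companion cell set 26 rose and 7 fell (median 0.89, adjusted p = 1.66e-12; adjusted p = 0.453 with an estimated correlation). The protophloem set had 7 rises between the first zones (median 0.54, adjusted p = 1.96e-13; adjusted p = 0.447 with an estimated correlation). The meristematic xylem set was called with medians of 0.23 and 0.09 in the comparisons against the meristematic zone (adjusted p = 0.00312 and 0.00384; adjusted p = 0.513 with an estimated correlation for both), but with 200 probe sets both calls were lost (adjusted p = 0.9), with the direction of the test turned. For J2501 from meristematic to maturation zone, and for meristematic xylem and companion cells from elongation to maturation zone, median and test differed in sign.

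The columella section was compared with meristematic section 1 of root 1, with 1 array on each side and no test. No probe set was at least 4-fold higher in it (0), and 484 were at least 4-fold lower. Its log2 values had an SD of 0.137 against 0.634 in the meristematic section. The difference followed the level in the meristematic section, with a Spearman correlation of -0.948 across probe sets. With so small a spread in the columella array, this follows from the subtraction and adds nothing to the SDs. Among the named genes the lowest were nad4 of the mitochondrion at -3.78, ATLP-1 at -3.49, rpl20 at -3.46, PMM at -3.38, MAB1 at -3.30, COR47 at -3.18, rps19 at -3.14 and psbM at -3.12. The highest were PMEPCRF, a pectin methylesterase gene, at 0.81, ZW9 at 0.74, SBT4.12 at 0.68, UGT71C1 at 0.57, AGL19 at 0.56, PDF2.1 at 0.55, MMP at 0.54 and SAT32 at 0.54. Apart from ZW9 (1.57 intensity units) and PMEPCRF (0.949), these lay below the median of the meristematic section array (0.937) in that array. PMM, rpl20 and ATLP-1 lay below the columella median (0.992) in the columella. Such dim values have an unknown background, so the differences are uncertain and their order is not read. The ribosomal protein median was -2.26 (percentile 0 of random lists), and the class III peroxidase median was 0.27 (percentile 100). After quantile normalization 49 probe sets were at least 4-fold higher and 55 lower, and COR47 stood at 0.06. Against the mean of both first meristematic sections 1 was higher and 1031 were lower. An offset of 1 gave 0 and 235, and an offset of 50 gave 0. The last was fixed in advance, since the highest value in the 2 arrays, 74.9, is too low for 4-fold at that offset.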

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

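The offset of 1, the omission of the 4 root 1 arrays of the lowest spread, and the list and population set runs without elongation section 2 of root 1 were chosen after array values had been seen. The added lists were chosen after the probe annotation was read and before any gene's values were seen. Where a count moved by over 1.5 times, the cause was not tested. Leaving out the dimmest 30% of probe sets left every count it was run on within 1.5 times. Signal over background limits what can be said of dim genes, since part of a low value can be background and an offset shrinks its log2 differences. The offset of 50 lies far above every array median (0.79 to 1.04), so a call lost with it can reflect that shrinkage alone. The 5 counts that follow are for elongation against meristematic, maturation against elongation and maturation against meristematic zone, then for variation and for steps, where they moved. With no replicate block they were 193, 79, 730, 2442 and 67. In the fit to all 24 arrays the zone counts were 3359, 884 and 7218. Quantile normalization gave 1018 and 69 for the first comparisons and 439 for the steps. The offset of 50 gave 206, 5, 451, 2114 and 529, and the offset of 1 gave 785, 57 and 1742 for the zones and 231 for the steps. A trended prior gave 654 for maturation against elongation and 286 for the steps, and without the 4 low-spread arrays these were 607 and 283. With single arrays left out the ranges were 564 to 2031, 46 to 472, 1609 to 3771, 2570 to 5122 and 71 to 824.

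List calls numbered 0 in both families with an estimated correlation, where 4 and 30 had been made, a run with 2 degrees of freedom and little power. They numbered 5 in the added family with fry and 7 in the fixed family after quantile normalization. Population sets numbered 0 with an estimated correlation and 0 with fry, against 17. Of the 34 called lists 33 kept the call without elongation section 2 of root 1 and 32 after quantile normalization, with the median of each on the same side of 0. Population-specific probe sets numbered 631 with the offset of 1 and 0 with the offset of 50, the latter fixed in advance by the range of the values. Columella differences numbered 104 after quantile normalization, 235 with the offset of 1 and 1032 against both roots. They numbered 0 with the offset of 50, also fixed in advance. COR47 turned to 0.064 after quantile normalization. With 200 probe sets the meristematic xylem set lost both calls (adjusted p = 0.9) and its test direction turned, at medians of 0.064 and -0.068 for elongation and maturation against the meristematic zone.

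Called lists reversed as well. With root 2 left out, the median of the class III peroxidase list and that of the plastid-encoded list, both called from elongation to maturation zone by camera (adjusted p = 0.00234 and 0.0126), changed sign. Lists were not tested in a root alone, so the medians do not say which root carried these calls. The other reversals were of genes that had not passed limma. Quantile normalization turned AUR2 to 0.0799, JKD to 0.356 and SBE2.2 to 0.00229 between the first zones, and APL3 to 0.0165 and ARR15 to 0.00371 from elongation to maturation. Without the 4 low-spread arrays JKD became 0.203 and RR16 -0.0511 in that last comparison. With a single array or a root left out, values between the first zones ranged from -0.119 to 0.057 for APL3, -0.066 to 0.00263 for ARR15, -0.374 to 0.112 for AUR2, -0.115 to 0.0576 for IAA30, -0.435 to 0.249 for JKD, -0.109 to 0.214 for RR16 and -0.232 to 0.0859 for SBE2.2. From elongation to maturation zone they ranged from -0.244 to 0.0128 for APL3, -0.172 to 0.0277 for ARR15, -0.456 to 0.0297 for AUR2, -0.736 to 0.254 for EXPA18, -0.494 to 0.19 for JKD, -0.22 to 0.308 for RR16 and -0.0854 to 1.86 for psbM. The peroxidase list median ranged from -0.112 to 0.211, and the plastid-encoded list median from -0.536 to 0.0713, over the runs with an array or a root left out. From meristematic to maturation zone the ranges were -0.314 to 0.0197 for APL3, -0.217 to 0.0147 for ARR15 and -0.0573 to 0.25 for RR16. The cause was not tested.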

Other observations

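The tests of array spread, of root tip tissue, of lateral root primordia and of order-keeping compression below were chosen after the result was seen. Along the root the median log2 intensity of the ER body genes was 0.89 in root 1 and 2.03 in root 2 at meristematic section 1, 1.048 and 0.055 at meristematic section 2, 0.09 and 0.14 at elongation section 1 and 3.35 and 2.58 at maturation section 3. Between the meristematic and elongation zones the list had no call (camera adjusted p = 0.0875). In the sorted arrays the same 7 genes stood high in lateral root primordia (median log2 difference 2.16, percentile 100 of random lists), companion cells (1.55, percentile 100) and hair cells (1.48, percentile 99.93), and low in meristematic xylem (-1.89, percentile 0). PYK10, the main ER body beta-glucosidase, reached 34.1 intensity units in lateral root primordia and 3.49 in meristematic xylem. Tubulin genes had their highest median at meristematic section 5 in root 1 (1.93) and at meristematic section 4 in root 2 (2.81). The wound and stress list was high in phloem pole pericycle (1.08, percentile 98.2) and low in meristematic xylem (-1.64, percentile 0.19).

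Plastid-encoded transcripts were higher in the protophloem and metaphloem array than in the other 7 sorted arrays, with a median log2 difference of 2.57 over 43 genes. Array spread as the whole source is argued against, since the median was 2.41 (bootstrap interval 1.98 to 2.52) after quantile normalization. The intervals given here resample the genes of a list, so they hold no variation between arrays. Green cells carried over, past a sort by fluorescence of the reporter, cannot be told apart from a higher organelle content: 8 nuclear photosystem genes had a median of -0.16 (-0.27 to -0.06), which met the bound set against green cells, but at 0.558 to 1.08 intensity units, around the array median of 0.892, they are too dim to exclude it. Priming of organelle RNA without a poly(A) tail may contribute, since 10 mitochondrial-encoded genes had a median of 2.07 (1.03 to 2.50), with nad4 at 2.68 and cox1 at 2.50; nad2 and nad7, at 0.08 and 0.11, were too dim to tell (0.523 and 0.560 intensity units). A higher organelle content of these cells stays open and was not tested, with 1 array for the population.

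Mitotic apparatus genes were higher in maturation section 4 than in the mean of the elongation sections and maturation section 1, by a median of 0.24 in root 1 and 0.83 in root 2, with 22 of 27 genes higher in both, while core histones (percentiles 93.5 and 73.8, 4 of 7 higher in both) and DNA replication enzymes (85.6 and 80.6, 3 of 7) did not stand out. In root 1 the mean compared against includes the array of elongation section 2, which stood apart from the other section arrays (log2 SD 0.426). The root 1 values of this comparison, and the counts of genes higher in both roots, were not computed without that array. Both mitotic medians lay at percentile 100 of random lists of the same level, which met the bound set against array spread. The random lists draw genes independently, while genes of a list can move together, so this does not settle whether array spread contributed. Root tip tissue is argued against, since the ribosomal protein genes, high at the tip, changed by 0.086 (bootstrap interval over genes 0.0020 to 0.159) in root 2 and -0.24 in root 1. A candidate explanation is lateral root primordia in that section: the 100 probe sets of their sorted array lay at percentile 100 in both roots (medians 0.10 and 0.29), while no other population lay above percentile 99 in both, the nearest being phloem pole pericycle at 98.3 and 99.96. The comparison leaves out maturation sections 2 and 3, and the primordia set did not mark section 4 in both roots. Its median log2 intensity at maturation sections 2, 3 and 4 was 0.19, 0.67 and 0.14 in root 1. In root 2 it was 0.70, 0.59 and 1.005. Primordia in that section stay a hypothesis, also since these percentiles too take no account of genes that move together. From elongation to maturation zone 8 of the 100 primordia probe sets also rose, 0 fell and 92 did not pass (median 0.31, camera adjusted p = 4.25e-11). That call was lost with an estimated correlation (adjusted p = 0.294) and with fry (adjusted p = 0.146). JAL33, among the 5 genes named for that array (7.66 to 15.9 intensity units in it), rose by 2.48 between these zones. The others of the 5 were not among the genes named for this comparison. JAL33 was 1.735-fold above the highest other array and is not among the 51 counted for primordia. It is also an ER body gene, and that list stood high in companion cells and hair cells too. Its rise therefore does not point to primordia. No sort preceded the sections, and the labels do not say whether either root bore primordia.

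The array of elongation section 2 of root 1 stood apart from the other section arrays. Compression of values that kept their order is argued against as the sole source, since its highest Spearman correlation with another section array was 0.620, against 0.860 to 0.955 for the other 23. Whether it is an array of root 2, as its description reads, cannot be told from its correlation with the difference between the roots. The correlation was taken after quantile normalization, which gives the arrays the same spread. It was 0.257, inside the range of 11 other root 1 arrays (-0.093 to 0.508) and above that of the 12 root 2 arrays (-0.447 to 0.168). As deposited, most root 1 arrays had a lower log2 SD than most root 2 arrays, however. This array had the lowest of the section arrays (0.426). Of the root 2 arrays, that of the lowest SD (meristematic section 6, 0.835) gave the 0.168. That of the next lowest SD (meristematic section 5, 0.891) gave -0.25. Low spread before normalization thus went with a value on the root 1 side in the first of these arrays and not in the second. A part of spread in the 0.257 is not excluded. Poor hybridisation or RNA quality may be the source and was not tested, and no biological explanation was tested.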
